A study of Homo sapiens with 28 samples.

How the data were processed

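RNA sequencing of 28 xenograft tumours grown in mice was read from 3 tables. C4-2-tet-shRB tumours gave 1 table without and 1 with doxycycline, each with 4 vehicle and 4 testosterone tumours, from experiments done independently per the series text. LuCaP 35CR tumours gave the third, with 3 tumours each for vehicle, palbociclib, testosterone and both. Doses per the labels were 160 mg/kg testosterone for C4-2, 40 mg/kg for LuCaP 35CR and 150 mg/kg palbociclib. The values are raw counts per gene and library as deposited by the authors, 57773 genes per table. Per the submitters' processing notes the tools were FastQC 0.11.9, STAR 2.7.2 and featureCounts 1.6.4, with the human builds hg19 and GRCh37. Strand setting, annotation release and handling of multi-mapping reads are not stated. No mouse genome is named, so mouse reads that aligned to human genes were not set apart. No coordinates are given, because the annotation at hand is on another build.

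XIST and genes on chromosome Y (518) were removed first. Symbols differed for 29 genes of the LuCaP table and were matched by Ensembl ID. Total counts per library were 5018348 to 10700178 without doxycycline, 7290100 to 16755048 with it and 4110687 to 5542805 for LuCaP 35CR. The labels give a total-RNA kit for the table without doxycycline and an mRNA kit for the others, but non-polyadenylated RNAs took 0.00859% to 0.0179% of counts without doxycycline, 5.13% to 7.62% with it and 0.00191% to 0.00905% in LuCaP 35CR. Kit, experiment and doxycycline thus cannot be told apart in C4-2.

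Each table was fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood test) with 1 coefficient per group, and the C4-2 interaction was fitted on both tables jointly. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 CPM used a prior count of 2. Tumour numbers were not treated as pairs: libraries of the same number correlated best with each other in 1 of 8 cases without doxycycline, 1 of 8 with it and 6 of 12 in LuCaP 35CR. The design and 35 gene lists were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 (preset correlation 0.01, and with an estimated correlation) and with fry. Single values and list scores were compared by two-sided exact permutation, whose smallest p is 0.0286 for 4 against 4 and 0.1 for 3 against 3. Floors use 3 counts over a group and cover counting error only.

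Genes were named by a fixed rule. Some genes that it selects are not reported here. It takes 10 fixed genes, up to 4 members per described list with the smallest adjusted p, and per comparison the 5 highest and 5 lowest called fold changes at a mean log2 CPM of at least 2 without overlap between groups, leaving out clone, LOC, pseudogene and mitochondrial names. A comparison without calls gives its 3 smallest adjusted p, and a gene named once may be quoted again. Few genes that went against the rest of their list, or were the only ones called, were named after their values were seen.

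In simulated counts with 2-fold changes, edgeR recovered 70.1% without doxycycline, 26.9% with it and 17.9% in the C4-2 interaction. LuCaP 35CR gave 58.2% to 62.7% in its pairs and 23.9% in its interaction. Of calls, 2.73% to 8.05% were false.

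Alternatives set beforehand were DESeq2 1.42.0, limma voom with sample weights, RLE and upper-quartile factors, a fit that is not robust, no filter, a filter at 1 CPM, a replicate block, removal of mitochondrial, histone and non-polyadenylated genes, only the groups compared, thinned libraries, an estimated correlation, other thresholds for overlaps and leaving out each library. A host score covariate (mean of fibroblast, endothelial and myeloid scores), removal of the transcript length trend and removal of the libraries labelled dox testosterone 3 and 4 were added after the data were seen.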

Results

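The series asks how castration-resistant prostate tumours grown in mice respond to high-dose testosterone (T), to the CDK4/6 inhibitor palbociclib (Pal) and to both drugs together, and whether the retinoblastoma gene RB1 matters for the response to T. C4-2-tet-shRB is a prostate cancer cell line that carries a doxycycline-induced hairpin against RB1, and LuCaP 35CR is a castration-resistant xenograft line. Changes are given as log2 fold change ± SE from edgeR, with adjusted p. Levels are CPM (counts scaled to library size) as mean ± SD over 4 tumours per C4-2 group and 3 per LuCaP 35CR group.

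The level of RB1 (ENSG00000139687), the target of the hairpin, did not separate the C4-2 tables as their labels would have it. The 4 libraries labelled no-dox vehicle had 7.06, 3.05, 27.3 and 2.92 CPM, and the 4 labelled no-dox testosterone had 19.3, 14.25, 17.5 and 17.1 CPM. The 4 labelled dox vehicle had 4.37, 5.28, 4.74 and 3.93 CPM, and the 4 labelled dox testosterone had 8.38, 7.59, 3.19 and 19.0 CPM. The libraries labelled no-dox vehicle 2 and 4 thus lay below every library labelled dox vehicle, and the library labelled dox testosterone 4 lay within the range of those labelled no-dox testosterone. The latter library also had the highest fibroblast, endothelial and myeloid scores of its group, given below, and mouse reads were not set apart. By edgeR, T against vehicle gave 0.81 ± 0.68 without doxycycline (adjusted p = 0.454, and 0.00475 without no-dox vehicle 3) and 1.05 ± 0.44 with it (adjusted p = 0.148). Over all 8 libraries of each table, dox minus no dox was -0.81 on the log2 scale (permutation test over 12870 arrangements, two-sided p = 0.134). It was -0.53 between the vehicle groups (exact permutation p = 0.657) and -1.09 between the testosterone groups (p = 0.114 by the same test). Within tables, testosterone minus vehicle was 1.35 without doxycycline (exact permutation p = 0.143) and 0.78 with it (exact permutation p = 0.171). The RB1 relatives moved otherwise: RBL1 was higher in the dox table by 0.74 (permutation p = 0.00186) and RBL2 differed by 0.02 (permutation p = 0.858). Without the library labelled no-dox vehicle 4, the RB1 difference was -1.06 with p = 0.048 by the same permutation test. The values therefore go against the labels in part, and the C4-2 groups are named below as they were labelled.

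**Figure D1:**
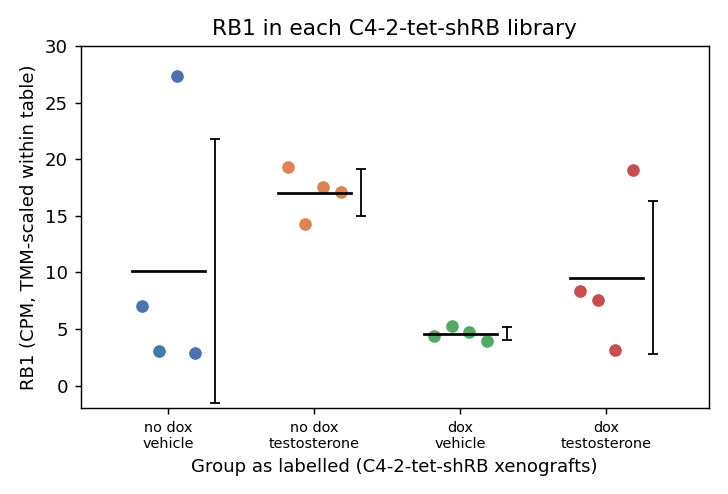
RB1 level in CPM (vertical axis) in each C4-2-tet-shRB library by labelled group (horizontal axis), where points are libraries, lines are means and bars are ± SD of 4 libraries. The libraries labelled no-dox vehicle span 2.92 to 27.3 CPM and those labelled dox vehicle 3.93 to 5.28 CPM.

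In C4-2 tumours labelled as without doxycycline, T lowered genes for DNA replication and cell division and raised a part of the androgen programme. Part of the genes of protein folding stress, lysosomes and antigen presentation rose as well, and so did most NF-kB targets, part of the fibroblast markers and most markers of vessels and myeloid cells. None of the list calls held with an estimated correlation. Of 15577 genes tested, 2849 were called, 1808 higher and 1041 lower. The direction rests on labels that the RB1 values go against in part.

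The replication genes, which license origins, copy DNA and supply nucleotides, fell in 39 of 50 measured cases, with 11 not called (47 fell when adjusted over the list alone). Among them were UHRF1 (-1.08 ± 0.14), ORC1 (-1.01 ± 0.20), DBF4 (-0.81 ± 0.16) and GINS4 (-0.66 ± 0.13). The fixed gene MCM7 (ENSG00000166508) dropped from 434 ± 48.8 to 269 ± 56.6 CPM (-0.69 ± 0.15, adjusted p = 0.00829). Of the E2F and checkpoint genes, 16 of 21 fell (19 adjusted over the list alone), with E2F2 (-1.13 ± 0.21), E2F7 (-1.09 ± 0.20), CHEK1 (-0.95 ± 0.19) and ASF1B (-1.0 ± 0.22). E2F1 (ENSG00000101412) was 113 ± 32.9 CPM against 209 ± 39.4 (-0.89 ± 0.20, adjusted p = 0.0143). Mitotic genes of the spindle and kinetochore fell in 33 of 40 cases (40 adjusted over the list alone), such as KIF11 (-0.91 ± 0.16), TTK (-0.85 ± 0.16), DLGAP5 (-0.84 ± 0.15) and BUB1B (-0.81 ± 0.15). The proliferation marker MKI67 (ENSG00000148773) went from 140.2 ± 18.6 to 81.3 ± 19.0 CPM (-0.79 ± 0.17, adjusted p = 0.00875). Homologous recombination and Fanconi genes, which mend broken forks, fell in 10 of 32 cases, 22 were not called, and 18 fell and 1 rose when adjusted over the list alone. Examples were UBE2T (-0.83 ± 0.19), FANCI (-0.69 ± 0.16), FANCD2 (-0.50 ± 0.13) and XRCC3 (-0.41 ± 0.10). The fixed cell-cycle regulators CCND1 (ENSG00000110092; 0.05 ± 0.12, adjusted p = 0.808), CDKN1A (ENSG00000124762; -0.44 ± 0.21, adjusted p = 0.167) and MYC (ENSG00000136997; 0.12 ± 0.24, adjusted p = 0.771) were not called.

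Of the genes that androgen agonists are known to raise, 9 of 39 rose, 29 were not called, and 1 fell (16 rose and 2 fell when adjusted over the list alone). ACPP, a secreted prostate phosphatase, went from 115.6 ± 21.4 to 607 ± 214 CPM (2.40 ± 0.24, adjusted p = 0.00145), and MAF (2.10 ± 0.25), PMEPA1 (1.04 ± 0.12) and RHOU (1.03 ± 0.14) rose too. KLK3 (ENSG00000142515), which encodes prostate-specific antigen, was 12599 ± 464 against 9581 ± 1343 CPM without a call (adjusted p = 0.0831, range over the alternatives 0.00619 to 0.855), and FKBP5 (ENSG00000096060; 0.29 ± 0.30, adjusted p = 0.552) was not called. Endoplasmic reticulum stress genes rose in 7 of 25 cases (9 adjusted over the list alone), led by the co-chaperone gene DNAJB9 (1.25 ± 0.15) with ATF3 (0.76 ± 0.18), HERPUD1 (0.53 ± 0.12) and SYVN1 (0.47 ± 0.11). Lysosome and autophagy genes rose in 9 of 24 cases and ATG4D (-0.41 ± 0.11) fell (10 and 1 adjusted over the list alone), with rises of HEXA (0.79 ± 0.13), SQSTM1 (0.70 ± 0.14), CTSD (0.64 ± 0.12) and CTSB (0.57 ± 0.11). NF-kB targets and secreted factors rose in 10 of 13 cases (11 adjusted over the list alone). GDF15, a stress-induced cytokine gene, went from 1175 ± 325 to 3847 ± 1567 CPM (1.71 ± 0.29), beside RELB (1.93 ± 0.36), BIRC3 (1.79 ± 0.33) and NFKB2 (1.14 ± 0.16). Antigen presentation genes rose in 7 of 17 cases (8 adjusted over the list alone), namely PSMB9 (1.41 ± 0.29) and TAPBP (0.61 ± 0.12) among others. HLA-F and HLA-B rose by 1.24 and 0.68, where reads shared between HLA genes make the source uncertain.

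Among the largest rises were ORM1 (6.97 ± 0.74, adjusted p = 0.00219) and ORM2 (5.6 ± 0.64), paralogs whose reads may be shared, followed by S100P (3.77 ± 0.64) and CRYM (3.44 ± 0.54) and U3 (3.30 ± 0.29), a small nucleolar RNA with several gene copies. Among the largest falls were the carbonic anhydrase genes CA1 (-3.60 ± 0.80) and CA2 (-2.82 ± 0.65) with GLYATL3 (-3.30 ± 0.54), PGLYRP2 (-3.05 ± 0.54) and FAM65B (-2.32 ± 0.55). Beside these changes, fibroblast markers rose in 9 of 20 cases (18 adjusted over the list alone), such as PDGFRB (2.19 ± 0.43), THY1 (2.02 ± 0.49), DCN (2.00 ± 0.44) and COL6A2 (1.47 ± 0.32). Endothelial markers rose in 11 of 13 (13 adjusted over the list alone), such as CLDN5 (2.90 ± 0.43), ROBO4 (2.81 ± 0.44), SOX18 (2.11 ± 0.30) and ENG (1.85 ± 0.27). Myeloid markers rose in 12 of 12 (12 adjusted over the list alone), such as CYBB (3.38 ± 0.51), AIF1 (2.54 ± 0.43), C1QA (2.19 ± 0.36) and FCER1G (2.09 ± 0.38). Of the ribosomal protein genes, 2 of 38 fell (RPS12, -0.50 ± 0.14, and RPSA, -0.45 ± 0.14, whose groups overlap in CPM) and 0 did when adjusted over the list alone. RPS12 lost the call without no-dox vehicle 2 or 4 or no-dox testosterone 1, 3 or 4 (adjusted p between 0.0576 and 0.0864), and RPSA without these or no-dox vehicle 1 (between 0.0588 and 0.106).

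Tested against the other genes with camera, the replication, E2F, mitotic and recombination lists stood lower, with medians of -0.67, -0.68, -0.77 and -0.47 and adjusted p = 5.69e-23, 1.97e-11, 9.18e-24 and 8.05e-07. With an estimated correlation these became adjusted p = 0.345, 0.345, 0.345 and 0.429. The androgen-induced, stress, lysosome, antigen presentation and NF-kB lists stood higher, with medians of 0.40, 0.23, 0.27, 0.37 and 1.71 and adjusted p = 4.81e-08, 0.00308, 0.00180, 0.00230 and 9.19e-09. They had adjusted p = 0.429, 0.434, 0.345, 0.433 and 0.345 with an estimated correlation. Fibroblast, endothelial and myeloid lists had medians of 1.97, 2.11 and 2.39 (adjusted p = 9.19e-09, 7.82e-13 and 3.03e-14, or 0.429, 0.345 and 0.345 with an estimated correlation). Ribosomal proteins had -0.28 (adjusted p = 1.6e-07, or adjusted p = 0.468 with an estimated correlation). With the host score as a covariate, edgeR called 0 genes (948 at an unadjusted p under 0.05, no other tool run with it). The stress, antigen presentation and ribosomal lists lost their calls, the stress list at adjusted p = 0.931. The count was 1790 without no-dox vehicle 4 and 1533 without no-dox testosterone 4. Single named calls ended without no-dox vehicle 4 (FANCD2, adjusted p = 0.0533, and XRCC3, 0.0525) or without no-dox testosterone 1, 3 or 4 (CA1, CA2 and FAM65B, between 0.0547 and 0.0861).

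In C4-2 tumours labelled as with doxycycline, T raised part of the androgen-induced genes, while replication and mitotic genes were not called. Part of the p53 targets fell, and part of the fibroblast, endothelial and myeloid markers rose. None of the list calls held with an estimated correlation. Of 16642 genes tested, 874 were called, 551 higher and 323 lower. DESeq2 called 2608 and limma voom 2017, and edgeR called 1432 without a filter and 312 with a block for the tumour number. This direction, too, rests on labels that the RB1 values go against in part.

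Androgen-induced genes rose in 12 of 40 cases and fell in 0 (12 adjusted over the list alone). NCAPD3, a condensin subunit gene, went from 41.8 ± 9.53 to 219 ± 48.4 CPM (2.39 ± 0.22, adjusted p = 0.00164). IGF1R, a growth factor receptor gene, went from 45.8 ± 8.30 to 144 ± 45.6 CPM (1.65 ± 0.23), and FKBP5, a steroid receptor co-chaperone gene, from 256 ± 32.6 to 575 ± 156 CPM (1.17 ± 0.22). HERC3 (1.19 ± 0.16) rose, and ORM1 was 2.02 against 0.0167 CPM, the latter from 1 count. KLK3 was not called (-0.35 ± 0.35, adjusted p = 0.533). Of the androgen-repressed genes, 2 of 5 fell (2 adjusted over the list alone), among them CAMK2N1 (-1.80 ± 0.33). Targets of p53, which halt growth or promote cell death, fell in 6 of 22 cases (10 adjusted over the list alone), with FAS (-1.51 ± 0.34), TP53INP1 (-1.32 ± 0.23), RRM2B (-1.31 ± 0.26) and BTG2 (-0.98 ± 0.20). Among the largest rises, ST6GAL1, a sialyltransferase gene, went from 1.56 ± 0.569 to 36.1 ± 21.1 CPM (4.53 ± 0.45, adjusted p = 0.00164). Complement gene C7 (6.34 ± 1.28) and the class II genes HLA-DRA (4.43 ± 1.02), HLA-DQA2 (4.37 ± 0.90) and HLA-DQA1 (4.33 ± 0.78) also ranked high, although reads shared between HLA paralogs leave the source of the latter uncertain. With T these genes were at 11.7 ± 16.7, 9.32 ± 12.3, 9.97 ± 12.7 and 8.32 ± 8.44 CPM in that order. Each SD exceeded its mean, so few libraries may carry these rises. Large falls included CA1 (-4.14 ± 0.89), PLA2G2A (-3.94 ± 0.79), GLYATL3 (-3.93 ± 0.76) and TMC5 (-3.37 ± 0.39) and the Wnt ligand gene WNT5A, from 488 ± 199 to 41.6 ± 26.1 CPM (-3.54 ± 0.53, adjusted p = 0.0106).

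No replication gene of 50, no E2F gene of 21 and no mitotic gene of 40 was called by edgeR (0 and 0, 0 and 0, and 0 and 0 up and down when adjusted over the list alone). MKI67 (-0.22 ± 0.20, adjusted p = 0.491), MCM7 (0.23 ± 0.26, 0.583), E2F1 (0.06 ± 0.20, 0.866), CCND1 (-0.25 ± 0.20, 0.416), CDKN1A (-0.69 ± 0.38, 0.256) and MYC (0.31 ± 0.30, 0.521) did not pass. The replication gene with the smallest adjusted p, POLD1, had 0.88 ± 0.31 with adjusted p = 0.0999. Of the recombination genes, FANCA rose (1.0 ± 0.25) and BARD1 fell (-0.85 ± 0.21) out of 32 (2 rose and 1 fell when adjusted over the list alone). Fibroblast markers rose in 8 of 20 cases (17 adjusted over the list alone), with COL1A1 at 4983 ± 4866 against 627 ± 178 CPM (2.99 ± 0.68) and COL1A2 (2.7 ± 0.62), SPARC (2.39 ± 0.54) and THY1 (2.24 ± 0.53). Endothelial markers rose in 6 of 12 (12 adjusted over the list alone), with CDH5 (3.15 ± 0.64), TIE1 (3.0 ± 0.62) and KDR (2.83 ± 0.63). Myeloid markers rose in 2 of 13 (13 adjusted over the list alone), with AIF1 (3.72 ± 0.86) and PTPRC (3.12 ± 0.73). The library labelled dox testosterone 4 stood highest on these scores. Its fibroblast score was 8.36 against 5.50 to 6.51 in the others of its group, its endothelial score 4.75 against 2.39 to 2.84 and its myeloid score 4.57 against 1.63 to 2.66. It was lowest on the luminal score, at 6.14 against 6.92 to 7.09. No ribosomal protein gene of 38 was called (0 adjusted over the list alone).

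With camera, the androgen-induced list stood higher (median 0.52, adjusted p = 1.66e-07, or adjusted p = 0.652 with an estimated correlation). The p53 list stood lower (median -0.42, adjusted p = 5.14e-05, or adjusted p = 0.652 with an estimated correlation). The androgen-repressed list had a median of -0.68 (adjusted p = 0.0118, or adjusted p = 0.652 with an estimated correlation) and lost its call without dox vehicle 1 to 4 or dox testosterone 4 (between 0.0516 and 0.234). Replication and E2F lists had medians of -0.05 and -0.02 without a call (adjusted p = 0.896 and 0.644). The mitotic list had a median of -0.24 (adjusted p = 0.0254, or adjusted p = 0.968 with an estimated correlation) and lost its call without dox vehicle 1 or 2 or dox testosterone 3 or 4 (between 0.188 and 0.495). With the host score as a covariate the replication list turned up with a call (adjusted p = 0.0194) and the mitotic list turned up without one (0.319), as it did without dox testosterone 3 and 4 (0.824). The recombination list differed in sign between its median of -0.01 and its mean of 0.03, with the test pointing up (adjusted p = 0.896). Fibroblast, endothelial and myeloid lists had medians of 2.17, 2.55 and 1.92 (adjusted p = 8.62e-08, 8.68e-08 and 1.73e-06, or 0.658, 0.652 and 0.658 with an estimated correlation). Ribosomal proteins had -0.47 (adjusted p = 8.62e-08, or adjusted p = 0.730 with an estimated correlation). This comparison was uneven between libraries. Its count was 304 without dox vehicle 1 and between 96 and 120 without dox vehicle 2, 3 or 4. It was 1565, 1935 and 228 without dox testosterone 1, 2 and 3. Of the called genes under the naming rule, 26 of 33 lost the call without at least 1 of dox vehicle 1 to 4 or dox testosterone 3 (adjusted p up to 0.153 for FANCA, which lost it without dox testosterone 4 as well). ST6GAL1, WNT5A, TMC5, HERC3, NCAPD3, IGF1R and ORM1 did not lose it in any of the 8. With the host score as a covariate 201 genes were called. Each of its marker scores separated T from vehicle here too, so the covariate can hardly be told apart from T.

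Whether the response to T differed between the C4-2 tables was tested as an interaction. The fall of replication genes with T tended to be smaller in the libraries labelled dox than in those labelled no dox, but no single gene passed and the list result depended on how correlation between genes was treated. Doxycycline, the separate experiment and the library kit cannot be told apart here, and the RB1 values go against the labels in part. Of 17533 genes edgeR called 0, with 2357 at an unadjusted p under 0.05, while DESeq2 called 164 and limma voom 71. Without a filter edgeR called 9, and with the host score as a covariate 47. The 3 genes with the smallest adjusted p, none of which passed, were APC2 (2.30 ± 0.38), TONSL (1.55 ± 0.27) and WDR62 (1.53 ± 0.26), each with adjusted p = 0.106. Fixed genes did not pass either: KLK3 -0.70 ± 0.40 (adjusted p = 0.476), FKBP5 0.92 ± 0.38 (0.321), MKI67 0.61 ± 0.28 (0.356), MCM7 0.97 ± 0.33 (0.256) and E2F1 0.99 ± 0.31 (0.230). Without dox testosterone 1 the count was 35 and took in APC2, TONSL and WDR62 (adjusted p = 0.0179, 0.0206 and 0.0204), and without no-dox vehicle 2 it was 1.

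Replication genes had a median difference of 0.66 (camera adjusted p = 2.40e-18, or adjusted p = 0.724 with an estimated correlation), with 0 of 50 called over all genes and 18 higher when adjusted over the list alone. Its members with the smallest adjusted p were UHRF1 (1.6 ± 0.35), POLD1 (1.48 ± 0.35) and CHAF1A (0.88 ± 0.23), the first pair at adjusted p = 0.158. The E2F, mitotic and recombination lists had medians of 0.65, 0.55 and 0.54 (camera adjusted p = 3.36e-08, 3.70e-08 and 6.92e-07, or 0.724, 0.724 and 0.724 with an estimated correlation), with 1 (E2F2, 1.42 ± 0.39), 0 and 5 genes higher when adjusted over the list alone, the last being FANCA, XRCC3, RAD54L, FANCG and FANCC. As a mean score per library, the replication difference was 0.65 (exact permutation over 4900 arrangements, p = 0.0706, adjusted p = 0.481 over the lists). The androgen-induced list had a median of 0.14 (adjusted p = 0.843, or adjusted p = 0.991 with an estimated correlation), and 1 gene was lower when adjusted over the list alone, ACPP (-2.62 ± 0.61, adjusted p = 0.158 over all genes). The luminal prostate list had a median of -0.32 (adjusted p = 0.000306, or adjusted p = 0.724 with an estimated correlation), with 1 gene lower when adjusted over the list alone, STEAP2 (-1.03 ± 0.29), and FOLH1 at -1.18 ± 0.38.

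**Figure D2:**
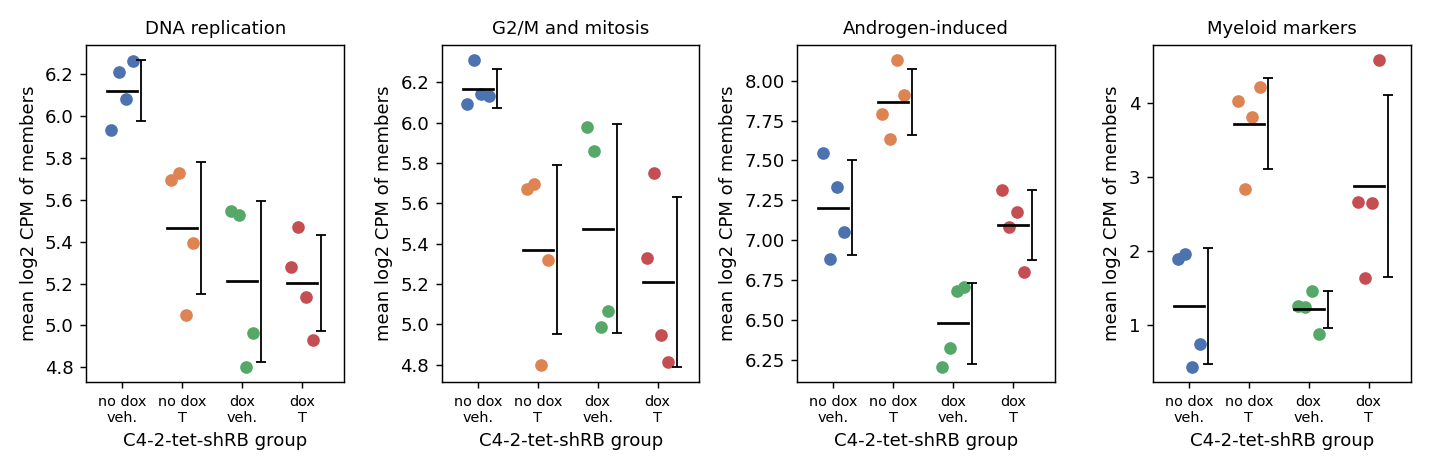
Mean log2 CPM of the members of 4 gene lists (vertical axes) in each C4-2-tet-shRB library by labelled group (horizontal axes), where points are libraries, lines are means and bars are ± SD of 4 libraries. The replication score averages 6.12 in libraries labelled no-dox vehicle and 5.47 in those labelled no-dox testosterone.

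The T responses of the C4-2 tables still shared genes. Among 15049 genes tested in both, 253 rose in both against 52.7 expected by chance (one-sided Fisher's exact test, p = 1.40e-117) and 105 fell in both against 20.2 (p = 1.92e-48). Another 1 and 5 went in opposite directions. Genes are not independent replicates, so these p-values are too small.

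In LuCaP 35CR tumours, Pal alone lowered mitotic and replication genes, and it raised most genes that androgens induce. Ribosomal protein genes and part of the genes for ribosome assembly, glycolysis and respiration fell. Most transcripts of the mitochondrial genome and part of the markers of fibroblasts, vessels and myeloid cells rose. Of the list calls, only the mitotic one held with an estimated correlation. Of 15430 genes tested, 5158 were called, 2612 higher and 2546 lower.

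All 40 mitotic genes fell. MKI67 went from 96.9 ± 14.8 to 3.27 ± 1.78 CPM (-4.93 ± 0.43, adjusted p = 3.43e-06), and the kinase and spindle genes PLK1 (-4.21 ± 0.25), KIF2C (-4.00 ± 0.24), KIF4A (-4.22 ± 0.25) and PTTG1 (-4.90 ± 0.24) moved alike. Replication genes fell in 44 of 50 cases (46 adjusted over the list alone), with TK1 (-3.19 ± 0.20), RRM1 (-1.67 ± 0.14), TYMS (-3.02 ± 0.27) and KIAA0101 (-4.47 ± 0.32) and MCM7 (-1.36 ± 0.19). E2F and checkpoint genes fell in 16 of 21 cases (18 adjusted over the list alone), with CCNA2 (-3.85 ± 0.39), MYBL2 (-4.09 ± 0.25), CHEK2 (-1.82 ± 0.26) and TFDP1 (-1.19 ± 0.14) and E2F1 (-1.11 ± 0.26). Recombination genes fell in 16 of 32 cases, with FANCD2 (-1.26 ± 0.17), FANCI (-1.76 ± 0.18), FANCG (-1.49 ± 0.19) and UBE2T (-2.46 ± 0.28), and RAD50 (0.49 ± 0.16) rose (19 and 1 adjusted over the list alone). RB1 rose (0.82 ± 0.23, adjusted p = 0.00912), CCND1, which pairs with CDK4 and CDK6, rose (0.55 ± 0.13), while MYC fell (-1.02 ± 0.25). The cell-cycle inhibitor gene CDKN1A was called (0.82 ± 0.27), with groups that overlap in CPM, and lost the call without vehicle 1, vehicle 2 or Pal 3 (adjusted p = 0.0906, 0.0812 and 0.179).

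Androgen-induced genes rose in 34 of 40 cases and SGK1 (-0.77 ± 0.29) and SNAI2 (-1.90 ± 0.35) fell (36 and 2 adjusted over the list alone). KLK3 went from 2540.2 ± 536 to 9950.4 ± 354 CPM (1.97 ± 0.18, adjusted p = 2.02e-07), and FKBP5 (1.76 ± 0.22), PMEPA1 (2.02 ± 0.18), ACPP (1.98 ± 0.17) and KCNMA1 (2.55 ± 0.25) rose too. Androgen-repressed genes fell in 3 of 6 cases (3 adjusted over the list alone), namely SI (-4.09 ± 0.51), AKR1C3 (-2.17 ± 0.43) and CAMK2N1 (-0.56 ± 0.20). CAMK2N1 lost its call without any vehicle library, Pal 3 or Pal+T 2 (adjusted p between 0.0505 and 0.213). Ribosome assembly genes fell in 14 of 28 cases (16 adjusted over the list alone), with NCL (-0.79 ± 0.15), FBL (-1.73 ± 0.20), NOP58 (-0.85 ± 0.14) and GNL3 (-0.79 ± 0.14). Ribosomal protein genes fell in 38 of 38 (38 adjusted over the list alone), with RPLP0 (-1.29 ± 0.19) and RPS23 (-1.36 ± 0.18). Glycolysis genes fell in 11 of 17 cases, with ALDOC (-1.30 ± 0.23), TPI1 (-1.09 ± 0.16), GAPDH (-1.10 ± 0.21) and PKM (-1.20 ± 0.18), and SLC16A3 (1.03 ± 0.37), a lactate exporter gene, rose (11 and 1 adjusted over the list alone). Nuclear genes of oxidative phosphorylation fell in 19 of 28 cases (20 adjusted over the list alone), with NDUFS3 (-0.97 ± 0.17), UQCRC1 (-0.89 ± 0.15), CYC1 (-0.98 ± 0.16) and COX4I1 (-1.05 ± 0.17). Transcripts of the mitochondrial genome rose in 12 of 13 cases (12 adjusted over the list alone), with MT-ND4L (1.90 ± 0.26), MT-ND5 (1.88 ± 0.28), MT-ATP6 (1.36 ± 0.21) and MT-ATP8 (1.67 ± 0.21). The share of all counts from the mitochondrial genome was 7.21% ± 0.701 against 3.24% ± 0.141 in vehicle tumours, and that from ribosomal protein genes 2.57% ± 0.746 against 5.92% ± 0.754.

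Among the largest rises were those of the cystatin gene CST2 (8.95 ± 0.83), whose paralogs share sequence, the xenobiotic enzyme gene CYP1A1 (6.77 ± 0.90) and GDA (5.32 ± 0.51). DNER was at 0 counts in vehicle tumours and at 2.89 ± 2.67 CPM with Pal, at least 15.4-fold higher over a floor of 3 counts for the group. HTR3C had 1 count in vehicle tumours and 17.7 ± 17.5 CPM with Pal. Among the largest falls were those of the mitotic genes GTSE1 (-5.03 ± 0.39), BIRC5 (-5.01 ± 0.34) and NUF2 (-4.98 ± 0.37). SPC25 and NMU went from 15.7 and 12.1 CPM to 2 counts each. Fibroblast markers rose in 8 of 16 cases (12 adjusted over the list alone), with COL1A1 (1.89 ± 0.43), COL6A3 (3.06 ± 0.38), PDGFRB (2.13 ± 0.62) and TAGLN (1.87 ± 0.20). Endothelial markers rose in 3 of 11 (3 adjusted over the list alone), namely KDR (2.07 ± 0.57), ENG (0.69 ± 0.16) and CLDN5 (1.52 ± 0.53). Myeloid markers rose in 6 of 7 (6 adjusted over the list alone), with CSF1R (1.85 ± 0.37), LYZ (2.84 ± 0.38), CTSS (1.37 ± 0.38) and CYBB (2.51 ± 0.77). PDGFRB lost the call without vehicle 1 (adjusted p = 0.0513), KDR without vehicle 2 or Pal 3 (0.0550 and 0.0518). CYBB lost it without these (0.0588 and 0.0655), CTSS without Pal 3 (0.0738), and CLDN5, whose groups overlap, without vehicle 2 or 3 or Pal 1 or 3 (between 0.0887 and 0.12).

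With camera, the mitotic list had a median of -3.37 (adjusted p = 1.13e-101) and kept its call with an estimated correlation (adjusted p = 0.00185). Replication, E2F and recombination lists had medians of -1.34, -1.19 and -0.84 (adjusted p = 1.76e-25, 1.48e-13 and 8.01e-06). These became adjusted p = 0.182, 0.182 and 0.327 with an estimated correlation. The androgen-induced list stood higher (median 1.49, adjusted p = 2.29e-23, or adjusted p = 0.124 with an estimated correlation). The androgen-repressed list stood lower (median -0.65, adjusted p = 0.0171, or adjusted p = 0.191 with an estimated correlation) and lost its call without vehicle 3, Pal 1, Pal 2, T 1, T 3 or Pal+T 1 (between 0.0513 and 0.105).

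Ribosome assembly, ribosomal protein, glycolysis, oxidative phosphorylation and mitochondrial genome lists had medians of -0.54, -1.18, -0.88, -0.60 and 1.30, with adjusted p = 2.36e-05, 1.46e-24, 0.00025, 2.51e-06 and 1.16e-09, or adjusted p = 0.387, 0.258, 0.356, 0.355 and 0.259 with an estimated correlation. Fibroblast, endothelial and myeloid lists had medians of 1.88, 1.52 and 2.17 (adjusted p = 2.36e-05, 0.0291 and 0.00462), and adjusted p = 0.327, 0.474 and 0.328 with an estimated correlation. The endothelial list lost its call without Pal 3 (adjusted p = 0.0549). Across genes, longer transcripts had higher fold changes (Spearman's rho = 0.31), and ribosomal protein genes had a median of -1.18 against -0.21 for genes of like length. With the host score as a covariate 1080 genes were called.

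T alone in LuCaP 35CR tumours raised most androgen-induced genes, lowered MYC, and raised part of the genes for lipid synthesis and polyamine metabolism. Part of the mitotic and replication genes fell, but MKI67 was not called. Ribosomal protein genes fell, and part of the fibroblast, endothelial and myeloid markers rose. Of the list calls, only those of the 2 androgen lists held with an estimated correlation. Of 15430 genes tested, 3835 were called, 2071 higher and 1764 lower.

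Androgen-induced genes rose in 36 of 40 cases and SGK1 (-0.81 ± 0.28) fell (38 and 1 adjusted over the list alone). KLK3 reached 9702 ± 548 against 2540.2 ± 536 CPM (1.93 ± 0.18), FKBP5 rose (2.13 ± 0.22), and so did SLC45A3 (3.12 ± 0.24), PMEPA1 (2.51 ± 0.19) and ACPP (2.03 ± 0.17). Of the androgen-repressed genes, 4 of 6 fell (4 adjusted over the list alone), among them SI (-4.79 ± 0.55), AKR1C3 (-1.68 ± 0.40) and CAMK2N1 (-1.22 ± 0.20). Genes for making and elongating fatty acids rose in 8 of 15 cases (8 rose and 1 fell when adjusted over the list alone), with ACSL3 (3.58 ± 0.21), ELOVL7 (0.92 ± 0.17), ELOVL5 (1.39 ± 0.19) and ME1 (0.90 ± 0.20). Genes of polyamine metabolism, both synthesis and breakdown, rose in 6 of 10 cases, with ODC1 (1.28 ± 0.18), SMS (0.65 ± 0.14), PAOX (1.29 ± 0.15) and SMOX (1.5 ± 0.24), and SRM (-0.55 ± 0.19) and OAZ1 (-0.43 ± 0.15) fell (6 and 2 adjusted over the list alone). CDKN1A rose (1.43 ± 0.27, adjusted p = 0.00122), MYC fell from 147 ± 27.4 to 29.996 ± 0.839 CPM (-2.29 ± 0.26, adjusted p = 1.71e-05), and CCND1 was not called (-0.19 ± 0.13, adjusted p = 0.312). RB1 was called (0.69 ± 0.23) but not without vehicle 1, vehicle 2 or T 3 (adjusted p = 0.104, 0.101 and 0.187).

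Mitotic genes fell in 14 of 40 cases (20 adjusted over the list alone), with KIF2C (-0.73 ± 0.19), CDC25C (-1.02 ± 0.23), CCNB2 (-0.77 ± 0.17) and PTTG1 (-1.04 ± 0.19). MKI67 was 113 ± 28.7 against 96.9 ± 14.8 CPM (0.23 ± 0.31, adjusted p = 0.644). Replication genes fell in 9 of 50 cases (6 adjusted over the list alone), with TK1 (-0.98 ± 0.18), MCM7 (-0.78 ± 0.19), LIG1 (-0.85 ± 0.21) and DUT (-0.65 ± 0.18). E2F genes fell in 3 of 21 (1 adjusted over the list alone), namely CHEK2 (-0.92 ± 0.24), MYBL2 (-0.61 ± 0.21) and TFDP1 (-0.43 ± 0.13). E2F1 was not called (-0.27 ± 0.25, adjusted p = 0.469). DUT lost its call without T 1 (adjusted p = 0.0607) and CHEK2 without vehicle 2 (0.0589). TFDP1 lost it without vehicle 1 or 3 or T 1 or 2 (between 0.0613 and 0.104), and MYBL2 without any vehicle or T library or Pal+T 3 (between 0.0519 and 0.144). Histone genes rose in 6 of 12 cases (8 adjusted over the list alone), with HIST1H1C (1.51 ± 0.21), HIST1H2BG (2.08 ± 0.28), HIST1H3D (2.16 ± 0.41) and HIST1H2AE (1.02 ± 0.28). Histone copies share sequence, and HIST1H2AE lost its call without vehicle 3 or T 2 (0.0628 and 0.0510). Interferon genes fell in 8 of 26 cases, with IFI44 (-2.25 ± 0.50), OASL (-2.54 ± 0.61) and MX1 (-1.78 ± 0.40), and the signal transducer gene STAT2 (1.0 ± 0.18) rose (8 and 1 adjusted over the list alone). All 38 ribosomal protein genes fell (38 adjusted over the list alone), such as RPS23 (-1.31 ± 0.18). Of the transcripts of the mitochondrial genome 12 of 13 rose (12 adjusted over the list alone), such as MT-ND5 (1.59 ± 0.28) and MT-ATP6 (1.11 ± 0.21).

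Among the largest rises was that of CYP1A1 (8.95 ± 0.90), with HTR3C at 1 count in vehicle tumours and 19.9 ± 9.79 CPM with T. PGC and SAA1 were at 0 counts in vehicle tumours and at 6.14 ± 2.40 and 5.38 ± 5.92 CPM with T, at least 32.6-fold and 28.6-fold higher over a floor of 3 counts for the group. SAA1, which has near-identical paralogs, lost its call without vehicle 1, 2 or 3 (adjusted p = 0.0665, 0.0671 and 0.0624). Among the largest falls were SLC3A1 (-6.07 ± 0.62), SCUBE2 (-5.32 ± 0.61) and MUC13 (-4.99 ± 0.46). OR51E2 and B3GALT1 went from 20.3 and 11.1 CPM to 2 counts and 1 count. Fibroblast markers rose in 8 of 16 cases (10 adjusted over the list alone), with COL1A1 (2.65 ± 0.44), COL1A2 (3.08 ± 0.58), COL6A3 (3.09 ± 0.38) and TAGLN (0.88 ± 0.20). Endothelial markers rose in 6 of 11 (8 adjusted over the list alone), with KDR (2.7 ± 0.56), VWF (3.59 ± 0.71), FLT1 (2.42 ± 0.70) and TEK (3.05 ± 0.82). Myeloid markers rose in 5 of 7 (7 adjusted over the list alone), with CSF1R (2.61 ± 0.36), LYZ (2.62 ± 0.38), CTSS (1.23 ± 0.38) and LAPTM5 (2.27 ± 0.58). FLT1 and CTSS lost the call without vehicle 2 or 3 or T 1 (adjusted p between 0.0528 and 0.111), and TEK and LAPTM5 without T 1 (0.0803 and 0.134).

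With camera, the androgen-induced and androgen-repressed lists had medians of 1.62 and -1.45 (adjusted p = 5.05e-42 and 1.05e-08) and kept their calls with an estimated correlation (adjusted p = 0.0153 and 0.00812). Replication, mitotic, lipid, polyamine and histone lists had medians of -0.40, -0.56, 0.90, 0.71 and 1.07 (adjusted p = 0.00059, 1.35e-06, 0.00026, 0.00516 and 0.000275). These became adjusted p = 0.602, 0.288, 0.276, 0.155 and 0.159 with an estimated correlation. The E2F list was not called (median -0.21, adjusted p = 0.153). The interferon list had a median of -0.56 (adjusted p = 0.0321, or adjusted p = 0.678 with an estimated correlation) and lost its call without vehicle 2, T 1 or T 2 (adjusted p = 0.460, 0.0552 and 0.0699). Fibroblast, endothelial, myeloid, mitochondrial genome and ribosomal protein lists had medians of 2.06, 1.92, 2.25, 1.03 and -1.16 (adjusted p = 3.65e-06, 0.00177, 0.000326, 2.35e-07 and 6.49e-29), and adjusted p = 0.288, 0.481, 0.276, 0.322 and 0.254 with an estimated correlation. With the host score as a covariate 366 genes were called.

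Given together, Pal and T changed more genes than either drug did against the same vehicle tumours. Cell-cycle genes fell to the lowest levels of the series' LuCaP 35CR groups on the list scores, and most androgen-induced, lysosome, lipid and basal epithelial genes rose. Of the list calls, only the mitotic one held with an estimated correlation. Of 15430 genes tested, 7958 were called, 3946 higher and 4012 lower.

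All 40 mitotic genes fell, MKI67 from 96.9 ± 14.8 to 3.55 ± 2.56 CPM (-4.74 ± 0.42, adjusted p = 1.04e-06), with PLK1 (-5.29 ± 0.28), KIF4A (-6.10 ± 0.31), PTTG1 (-6.52 ± 0.28) and CCNB2 (-4.37 ± 0.22). Replication genes fell in 47 of 50 cases (48 adjusted over the list alone), with TK1 (-3.82 ± 0.21), TYMS (-4.26 ± 0.30), RRM1 (-1.96 ± 0.14) and KIAA0101 (-4.96 ± 0.33) and MCM7 (-2.17 ± 0.20). E2F genes fell in 18 of 21 (18 adjusted over the list alone), with CCNA2 (-4.10 ± 0.40), MYBL2 (-5.25 ± 0.28), SKP2 (-1.93 ± 0.20) and TFDP1 (-1.43 ± 0.14) and E2F1 (-2.35 ± 0.28). Recombination genes fell in 22 of 32 cases, with BRIP1 (-3.50 ± 0.37), FANCI (-2.11 ± 0.18), FANCG (-2.49 ± 0.21) and UBE2T (-4.16 ± 0.33), and RAD50 (0.58 ± 0.16) rose (22 and 1 adjusted over the list alone). MYC fell from 147 ± 27.4 to 11.6 ± 3.35 CPM (-3.65 ± 0.29, adjusted p = 5.44e-08), CDKN1A and CCND1 rose (1.75 ± 0.27 and 0.60 ± 0.13), and RB1 was not called (0.40 ± 0.23, adjusted p = 0.154).

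Androgen-induced genes rose in 35 of 40 cases and CHRNA2 (-1.46 ± 0.15) and SNAI2 (-1.21 ± 0.33) fell (35 and 2 adjusted over the list alone). KLK3 was 10626 ± 676 CPM (2.06 ± 0.18), FKBP5 rose (3.49 ± 0.24, adjusted p = 2.61e-09), and EAF2 (5.42 ± 0.37), SORD (2.81 ± 0.18) and GREB1 (3.44 ± 0.23) rose too. Of the androgen-repressed genes 4 of 6 fell (4 adjusted over the list alone), among them HSD17B6 (-2.68 ± 0.30) and CAMK2N1 (-2.62 ± 0.21) and SI, which was at 0 counts and at least 53-fold lower over a floor of 3 counts for the group. Lipid synthesis genes rose in 11 of 15 cases, with FASN (3.08 ± 0.33), ACSL3 (4.27 ± 0.21) and ME1 (1.63 ± 0.20), and ELOVL6 (-1.62 ± 0.18) fell (11 and 1 adjusted over the list alone). Lysosome and autophagy genes, which serve recycling, rose in 20 of 24 cases, with CTSD (1.78 ± 0.19), GABARAPL1 (1.54 ± 0.19), WIPI1 (2.09 ± 0.20) and NPC1 (1.93 ± 0.18), and ATG4D (-0.56 ± 0.17) fell (20 and 1 adjusted over the list alone). All 7 basal epithelial genes rose (7 adjusted over the list alone), with KRT14 (4.88 ± 0.49), ITGB4 (2.31 ± 0.30) and DST (1.58 ± 0.14) and KRT15 at 4.75 ± 0.741 CPM against 1 count. All 38 ribosomal protein genes fell, such as RPL5 (-1.86 ± 0.17), RPLP0 (-2.11 ± 0.19) and RPS23 (-1.93 ± 0.19). All 13 transcripts of the mitochondrial genome rose, such as MT-ND2 (1.89 ± 0.21), MT-ND5 (2.75 ± 0.29) and MT-ATP6 (2.14 ± 0.22), with the same counts adjusted over the list alone.

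Among the largest rises was that of CYP1A1 (10.86 ± 0.93). SAA1, PGC and DNER were at 0 counts in vehicle tumours and at 67.8 ± 17, 45.3 ± 18.9 and 30.002 ± 6.40 CPM, at least 361-fold, 241-fold and 159.5-fold higher over a floor of 3 counts for the group, SAA1 with near-identical paralogs. NMU was at 0 counts with Pal+T, at least 57.6-fold lower than 12.1 ± 3.22 CPM in vehicle tumours. HSD17B13, NCAPG and MEP1A went from 30.4, 21 and 17.2 CPM to 1 count each. The antisense transcript TRHDE-AS1 fell (-7.13 ± 0.50), though the counting strand is not stated. Fibroblast markers rose in 14 of 16 cases (14 adjusted over the list alone), with COL6A1 (0.78 ± 0.15), COL6A2 (1.56 ± 0.20), COL6A3 (3.87 ± 0.37) and TAGLN (1.30 ± 0.20). Endothelial markers rose in 8 of 11 (9 adjusted over the list alone), with KDR (2.50 ± 0.56), ENG (1.16 ± 0.16), EGFL7 (0.73 ± 0.17) and CLDN5 (1.86 ± 0.52). Myeloid markers rose in 6 of 7 (6 adjusted over the list alone), with CSF1R (2.23 ± 0.36), LYZ (3.74 ± 0.38), CTSS (2.48 ± 0.37) and CYBB (2.87 ± 0.75), the last with groups that overlap. The mitochondrial share of counts was 9.52% ± 2.22 and the ribosomal protein share 1.48% ± 0.0949.

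With camera, the mitotic list had a median of -4.46 (adjusted p = 1.31e-73) and kept its call with an estimated correlation (adjusted p = 0.00335). Replication, E2F, recombination, lipid, lysosome and basal lists had medians of -1.99, -1.97, -1.73, 0.98, 0.87 and 2.31 (adjusted p = 1.63e-23, 8.59e-13, 6.11e-07, 0.000124, 1.79e-06 and 0.000113). These became adjusted p = 0.186, 0.186, 0.261, 0.216, 0.274 and 0.152 with an estimated correlation. The androgen-induced and androgen-repressed lists had medians of 2.00 and -2.56 (adjusted p = 2.55e-24 and 0.000124), or adjusted p = 0.0625 and 0.0525 with an estimated correlation. Fibroblast, endothelial, myeloid, mitochondrial genome and ribosomal protein lists had medians of 2.36, 1.86, 2.32, 1.93 and -1.85 (adjusted p = 0.000232, 0.0239, 0.0111, 4.53e-11 and 7.68e-27), and adjusted p = 0.350, 0.431, 0.350, 0.216 and 0.216 with an estimated correlation. The endothelial list lost its call without Pal+T 3 (adjusted p = 0.0565). With the host score as a covariate 3268 genes were called.

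**Figure D3:**
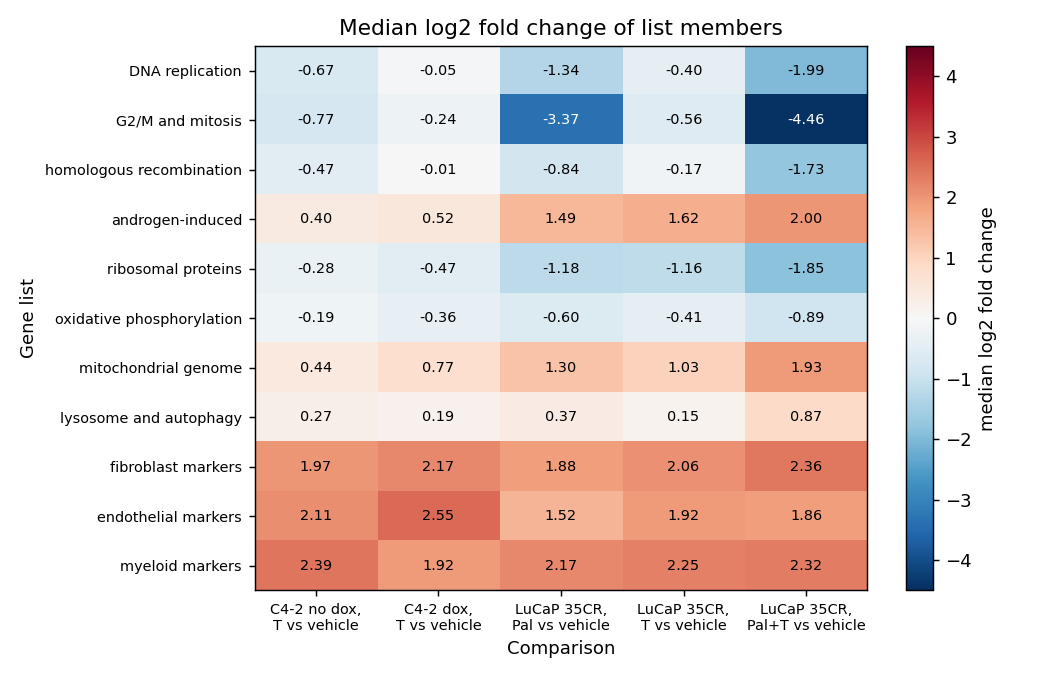
Heatmap of the median log2 fold change (colour scale) of 11 gene lists (vertical axis) in 5 comparisons with vehicle (horizontal axis). Mitotic genes have medians of -3.37 with Pal and -4.46 with Pal+T in LuCaP 35CR, against -0.56 with T alone.

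Adding Pal to T lowered cell-cycle genes. Most lysosome genes and NF-kB targets rose, and so did part of the antigen presentation and interferon genes. Of the list calls, only the mitotic one held with an estimated correlation. Of 15430 genes tested, 4462 were called, 2164 higher and 2298 lower than with T alone.

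All 40 mitotic genes fell, with MKI67 at 3.55 ± 2.56 against 113 ± 28.7 CPM (-4.96 ± 0.42, adjusted p = 2.83e-06) and PLK1 (-4.97 ± 0.28), CENPF (-4.84 ± 0.29), KIF4A (-5.77 ± 0.31) and PTTG1 (-5.48 ± 0.29). Replication genes fell in 46 of 50 cases (47 adjusted over the list alone), with TK1 (-2.83 ± 0.20), TYMS (-3.72 ± 0.30), RRM1 (-1.6 ± 0.14) and KIAA0101 (-4.42 ± 0.33) and MCM7 (-1.39 ± 0.19). E2F genes fell in 19 of 21 (21 adjusted over the list alone), with CCNA2 (-3.78 ± 0.40), MYBL2 (-4.64 ± 0.27), SKP2 (-1.74 ± 0.20) and HELLS (-3.49 ± 0.43) and E2F1 (-2.08 ± 0.28). Recombination genes fell in 21 of 32 cases, with XRCC3 (-1.61 ± 0.21), FANCI (-1.76 ± 0.18), FANCG (-1.94 ± 0.21) and UBE2T (-3.43 ± 0.33), and RAD50 (0.46 ± 0.16) rose (22 and 1 adjusted over the list alone). MYC fell (-1.36 ± 0.29), CCND1 rose (0.80 ± 0.13), and CDKN1A (0.33 ± 0.26, adjusted p = 0.372) and RB1 (-0.29 ± 0.22, adjusted p = 0.356) were not called. Androgen-induced genes rose in 20 of 40 cases and fell in 7 (22 and 7 adjusted over the list alone), with rises of FKBP5 (1.37 ± 0.22), RHOU (1.03 ± 0.14), SORD (1.6 ± 0.18) and GREB1 (1.96 ± 0.20) and a fall of CHRNA2 (-2.39 ± 0.15). KLK3 was not called (0.13 ± 0.17, adjusted p = 0.616).

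NF-kB targets rose in 11 of 13 cases (11 adjusted over the list alone), with TNFAIP3 (2.44 ± 0.29), TNFAIP2 (1.17 ± 0.19) and BIRC3 (3.43 ± 0.50) and the chemokine gene CCL20 at 2.89 ± 0.798 CPM against 1 count. Antigen presentation genes rose in 9 of 17 (11 adjusted over the list alone), with B2M (1.87 ± 0.26), TAPBP (1.03 ± 0.16) and ERAP1 (0.81 ± 0.17). Interferon genes rose in 7 of 26 (8 adjusted over the list alone), with DDX58 (1.12 ± 0.26), IFIH1 (0.85 ± 0.22) and SAMD9 (2.77 ± 0.61). Lysosome genes rose in 17 of 24, with CTSB (1.23 ± 0.17), CTSD (1.24 ± 0.19), SQSTM1 (1.43 ± 0.20) and NPC1 (1.18 ± 0.17), and TFEB (-1.13 ± 0.32) fell (18 and 1 adjusted over the list alone). Ribosomal protein genes fell in 29 of 38 cases (35 adjusted over the list alone), such as RPL4 (-1.06 ± 0.19), RPLP0 (-0.93 ± 0.19), RPS24 (-1.03 ± 0.21) and RPSA (-1.08 ± 0.23). Genes with large rises were UCA1 (5.01 ± 0.87), SPINK13 (3.88 ± 0.55), PAEP (3.77 ± 0.92) and F3 (3.65 ± 0.66) and SAA1 (3.67 ± 0.70). Large falls included ASPM (-5.96 ± 0.39) and FFAR4 (-5.95 ± 0.44) beside KIF4A. NCAPG was at 1 count against 16.8 ± 2.13 CPM and NMU at 0 counts, at least 19.0-fold lower than with T alone.

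With camera, the mitotic list had a median of -3.89 (adjusted p = 6.02e-119) and kept its call with an estimated correlation (adjusted p = 0.000312). Replication, E2F, recombination and ribosomal protein lists had medians of -1.49, -1.74, -1.53 and -0.68 (adjusted p = 2.54e-31, 1.18e-20, 4.20e-10 and 1.01e-08). These became adjusted p = 0.180, 0.169, 0.284 and 0.524 with an estimated correlation. Androgen-induced, lysosome, NF-kB, antigen presentation and interferon lists had medians of 0.48, 0.61, 1.36, 0.63 and 0.68 (adjusted p = 0.00366, 2.46e-07, 1.99e-06, 5.16e-05 and 0.00517), and adjusted p = 0.526, 0.319, 0.284, 0.319 and 0.599 with an estimated correlation. Fibroblast, endothelial and myeloid lists were not called (adjusted p = 0.335, 0.753 and 0.632), the endothelial one with a median of -0.20 and a mean of -0.08 where the test pointed up.

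Adding T to Pal lowered part of the cell-cycle genes further, lowered MYC, and raised part of the lipid, hypoxia and basal epithelial genes. None of the list calls held with an estimated correlation. MKI67 and KLK3 were not called. Of 15430 genes tested, 2896 were called, 1438 higher and 1458 lower than with Pal alone, and 1851 were called without Pal 2.

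MYC fell from 72.3 ± 30.6 to 11.6 ± 3.35 CPM (-2.63 ± 0.29, adjusted p = 1.09e-05). Mitotic genes fell in 24 of 40 cases (26 adjusted over the list alone), with CENPE (-1.39 ± 0.22), NEK2 (-3.13 ± 0.46), ASPM (-3.14 ± 0.47) and CCNB2 (-2.57 ± 0.23), but MKI67 was not called (0.20 ± 0.56, adjusted p = 0.859). Replication genes fell in 21 of 50 cases, with MCM3 (-0.96 ± 0.18), MCM7 (-0.81 ± 0.19), ORC6 (-1.74 ± 0.30) and GINS4 (-1.13 ± 0.24), and GINS3 (1.23 ± 0.24) rose (23 and 1 adjusted over the list alone). E2F genes fell in 6 of 21 (11 adjusted over the list alone), with E2F1 (-1.24 ± 0.28), SKP2 (-0.90 ± 0.20) and MYBL2 (-1.16 ± 0.30) and E2F7 at 3 counts against 5.08 ± 3.47 CPM. Recombination genes fell in 8 of 32 (9 adjusted over the list alone), with XRCC3 (-0.92 ± 0.22), FANCG (-1.0 ± 0.21), UBE2T (-1.70 ± 0.37) and RMI1 (-0.97 ± 0.21). MYBL2 lost its call without Pal 2 (adjusted p = 0.0509). CDKN1A was called (0.94 ± 0.26) but not without Pal 1, Pal 2 or Pal+T 1 (0.0952, 0.0741 and 0.0896), while CCND1 (0.05 ± 0.13, adjusted p = 0.838) and RB1 (-0.42 ± 0.22, adjusted p = 0.212) were not.

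Androgen-induced genes rose in 19 of 40 cases, with FKBP5 (1.73 ± 0.22), EAF2 (2.75 ± 0.29), SORD (1.77 ± 0.18) and GREB1 (1.71 ± 0.20), and 4 fell, among them SLC45A3 (-0.73 ± 0.22), CHRNA2 (-2.14 ± 0.15) and TSC22D3 (-1.01 ± 0.22) (22 and 5 adjusted over the list alone). KLK3 was not called (0.09 ± 0.17, adjusted p = 0.768). Androgen-repressed genes fell in 4 of 6 cases, among them SI, which was at 0 counts, with HSD17B6 (-2.27 ± 0.31) and CAMK2N1 (-2.06 ± 0.20), and AKR1C3 (2.48 ± 0.43) rose (4 and 1 adjusted over the list alone). Lipid synthesis genes rose in 7 of 15 cases, with FASN (1.88 ± 0.32), SREBF1 (1.26 ± 0.21) and ACSL3 (1.5 ± 0.19), and ELOVL6 (-1.19 ± 0.18) fell (9 and 2 adjusted over the list alone). Hypoxia genes rose in 8 of 20, with EGLN3 (2.88 ± 0.61), NDRG1 (1.06 ± 0.20) and BNIP3L (0.80 ± 0.17), and CA12 (-1.39 ± 0.27) fell (10 and 3 adjusted over the list alone). Basal genes rose in 5 of 7 (5 rose and 1 fell when adjusted over the list alone), namely KRT14 (2.63 ± 0.41), KRT15 (3.04 ± 0.69), ITGB4 (1.69 ± 0.29) and DST (0.67 ± 0.14) and NGFR (2.57 ± 0.67). Ribosomal protein genes fell in 25 of 38 (29 adjusted over the list alone), such as RPL4 (-1.08 ± 0.19), RPL5 (-0.82 ± 0.17), RPLP0 (-0.82 ± 0.19) and RPS24 (-0.91 ± 0.21). Among the largest rises were ITGA1 (7.33 ± 0.44), RHAG (7.11 ± 0.69) and PGC (6.90 ± 0.50) and CYP2A6 (7.26 ± 1.0), which has close paralogs, with CCDC141 at 20.5 ± 3.94 CPM against 2 counts. Genes with large falls were CDC20B (-6.16 ± 0.65) and B3GNT6 (-5.65 ± 0.94). MEP1A and HSD17B13 were at 1 count each against 8.14 and 5.54 CPM and SLC3A1 at 3 counts against 12.5 ± 8.68 CPM.

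With camera, the replication, E2F, mitotic, recombination and ribosomal protein lists had medians of -0.71, -0.76, -1.13, -0.73 and -0.65 (adjusted p = 7.88e-06, 0.00034, 2.01e-10, 0.00126 and 1.0e-09). These became adjusted p = 0.507, 0.507, 0.335, 0.507 and 0.507 with an estimated correlation. Androgen-induced, androgen-repressed, lipid, hypoxia and basal lists had medians of 0.70, -2.16, 0.52, 0.69 and 1.69 (adjusted p = 2.13e-09, 0.000137, 0.000226, 0.00383 and 0.00093), and adjusted p = 0.335, 0.0900, 0.363, 0.507 and 0.335 with an estimated correlation, and the androgen-repressed median was -1.81 with genes at 0 counts set to their bound.

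The interaction asks where the Pal effect differed with and without T. Part of the androgen-induced genes, most of which each drug raised alone, rose less than the sum of both effects. Part of the glycolysis, NF-kB and antigen presentation genes lay above that sum in log2. With both drugs some exceeded vehicle (TAPBP, 209 against 141 CPM), and some did not (ALDOA, 1273 against 1346). None of the list calls held with an estimated correlation. Of 15430 genes tested, 1374 were called, 522 positive and 852 negative.

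KLK3 stood at 2540.2, 9950.4, 9702 and 10626 CPM with vehicle, Pal, T and Pal+T (-1.84 ± 0.25, adjusted p = 8.00e-05). Of the androgen-induced genes 17 of 40 were negative, with PMEPA1 (-2.53 ± 0.25), CHRNA2 (-3.07 ± 0.21) and KCNMA1 (-2.99 ± 0.34) and SLC45A3 at 102, 463, 883 and 279 CPM in the same order (-3.85 ± 0.32), and SGK1 (1.71 ± 0.41) was positive (22 and 2 adjusted over the list alone). FKBP5 (-0.39 ± 0.30, adjusted p = 0.483), MKI67 (-0.03 ± 0.68, 0.986), MCM7 (-0.03 ± 0.27, 0.958), CCND1 (0.24 ± 0.19, 0.478), CDKN1A (-0.49 ± 0.37, 0.479) and MYC (-0.35 ± 0.38, 0.646) were not called. E2F1 (-0.97 ± 0.38, adjusted p = 0.126) was called only without Pal 1 (0.00945). RB1 was called (-1.11 ± 0.32) but not without vehicle 1 or 2, Pal 2, T 3 or Pal+T 1 or 2 (adjusted p between 0.0631 and 0.108). Mitotic genes were negative in 7 of 40 cases (7 adjusted over the list alone), with CCNB2 (-1.80 ± 0.29), ASPM (-2.52 ± 0.54), NEK2 (-2.27 ± 0.54) and ANLN (-1.89 ± 0.48), the last not without Pal 1 (0.0525). Of the replication genes GINS3 (1.23 ± 0.33) was positive out of 50 (0 adjusted over the list alone). It was not called without Pal 1, T 1 or 3 or Pal+T 2 or 3 (between 0.0523 and 0.0659). Of 21 E2F genes E2F7 was negative, at 10.7, 5.08, 9.22 and 0.211 CPM with 3 counts in the last (1 adjusted over the list alone).

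Glycolysis genes were positive in 7 of 17 cases, with ALDOC (1.43 ± 0.32), ALDOA (1.46 ± 0.35) and ENO2 (2.75 ± 0.69), and PFKM (-0.90 ± 0.22) was negative (11 and 1 adjusted over the list alone). ENO2 lost its call without Pal 1 or T 3 (adjusted p = 0.0501 and 0.0521). Hypoxia genes were positive in 6 of 20 cases, with KDM3A (0.88 ± 0.20), and CA12 (-1.80 ± 0.38), STC2 (-2.04 ± 0.57) and AK4 (-0.83 ± 0.18) were negative (9 and 4 adjusted over the list alone). NF-kB targets were positive in 5 of 13 (6 positive and 1 negative when adjusted over the list alone), namely NFKBIA (1.01 ± 0.21), TNFAIP3 (1.58 ± 0.41) and RELB (1.5 ± 0.41), BIRC3 (2.94 ± 0.73) and CCL20 at 3.35, 0.396, 0.0675 and 2.89 CPM, the value with T from 1 count. Antigen presentation genes were positive in 4 of 17 (5 adjusted over the list alone), with TAPBP (0.95 ± 0.23), PSMB8 (1.13 ± 0.28) and NLRC5 (1.53 ± 0.42). TNFAIP3 lost its call without vehicle 2 or T 1 (0.0915 and 0.0624), RELB without vehicle 2, Pal 2, T 1 or Pal+T 2 (between 0.0509 and 0.0904), and PSMB8 without vehicle 2 or Pal+T 2 (0.0526 and 0.0580). NLRC5 lost it without vehicle 1 or 2, Pal 1 or 2, T 1 or Pal+T 2 (between 0.0531 and 0.0844).

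Among the most positive values were those of VOPP1 (4.55 ± 0.72), ROBO1 (4.07 ± 0.72) and HK2 (4.28 ± 1.06). MUC13 stood at 22.9, 2.74, 0.690 and 2.73 CPM (4.98 ± 0.66) and AKR1C3 at 6.15, 1.37, 1.92 and 7.64 CPM (4.16 ± 0.59). HK2 lost its call without vehicle 1, Pal 1 or 2, or any T library or Pal+T 1 or 2 (adjusted p between 0.0580 and 0.0933). Among the most negative were KCNK3 (-7.51 ± 0.72) and CST2 (-8.13 ± 0.96). The peptide hormone gene CCK stood at 17.1, 559, 583 and 96.9 CPM (-7.62 ± 0.47, adjusted p = 8.57e-07) and DEPDC1 at 67.9, 402, 366 and 18.2 CPM (-6.89 ± 0.81). HTR3C, with 1 count in vehicle tumours, stood at 0.0621, 17.7, 19.9 and 31.8 CPM and lost its call without any vehicle or Pal+T library, Pal 1, or T 2 or 3 (between 0.0521 and 0.121).

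With camera, the androgen-induced, glycolysis, NF-kB and antigen presentation lists had medians of -0.89, 0.79, 1.01 and 0.48 (adjusted p = 2.87e-14, 1.61e-05, 0.00104 and 0.00116). These became adjusted p = 0.587, 0.587, 0.587 and 0.587 with an estimated correlation. The mitotic list had a median of -0.54 (adjusted p = 0.00987, or adjusted p = 0.770 with an estimated correlation) and lost its call without Pal 2 or Pal+T 1 (0.0878 and 0.109). The hypoxia list had a median of 0.77 (adjusted p = 0.0119, or adjusted p = 0.770 with an estimated correlation) and lost it without vehicle 2 or Pal 2 (0.109 and 0.0727). Replication and E2F lists were not called (medians -0.22 and -0.57, adjusted p = 0.353 and 0.0688) but were without Pal 1 (0.000686 and 0.00021), the E2F list also without vehicle 3, Pal+T 2 or Pal+T 3 (0.0367, 0.0498 and 0.0414). With the host score as a covariate 373 genes were called.

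**Figure D4:**
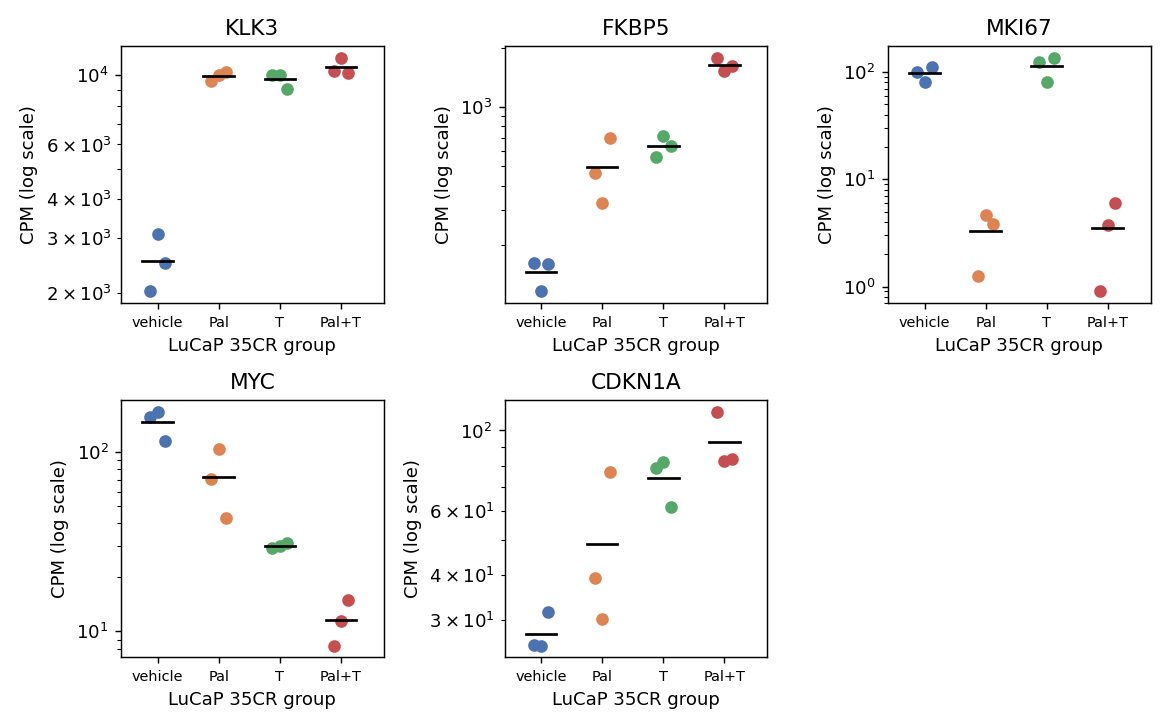
Level in CPM on a log scale (vertical axes) of KLK3, FKBP5, MKI67, MYC and CDKN1A in LuCaP 35CR tumours by treatment group (horizontal axes), where points are the 3 tumours of each group and lines are means. MKI67 averages 96.9 with vehicle, 113 with T and 3.55 CPM with Pal+T.

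Pal and T, each against the same 3 vehicle tumours, shared 1474 genes that rose and 1136 that fell, with 351 and 291 expected if they were independent. Their fold changes correlated across genes (Pearson's r = 0.748), and 20 simulations with no true effect but a shared vehicle group gave 0.49 on average. The covariance of the fold changes was 0.707, against 0.0745 in the simulations. The 3 vehicle tumours cannot be split into separate controls, so the part of the overlap that rests on them was not measured directly. The T responses of LuCaP 35CR and of the C4-2 libraries labelled no dox, which share no samples, had 493 genes higher in both of 13375 tested in both, with 174 expected (one-sided Fisher's exact test, p = 6.96e-125), and 239 lower in both, with 109.5 expected (p = 2.99e-34). Another 60 and 39 went in opposite directions, and genes are not independent replicates.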

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

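Of the tests below, that on an exchange with the testosterone group was chosen only after the result was seen, and so was the pair of loci. A library far from the others was looked for with 22 measures in each of the 4 C4-2 groups. Of these 88 tests, which are not independent, 3 stood out, where chance gives about 1 in 20, or 4.4.

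The library labelled no-dox vehicle 3 had 27.3 CPM of RB1, against 2.92 to 7.06 in the others of its group. In the same group, the lowest endothelial score was 1.36, against 1.93 to 2.02. Among the libraries labelled dox testosterone, 1 had 10.6% of its counts on a pair of clone-named loci, against 0.476% to 1.85%. The T effect on the luminal prostate list was -0.35 with and 0.16 without doxycycline, a difference of -0.50 (exact permutation p = 0.0127, adjusted p = 0.418 over the lists), which does not pass the correction.

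RB1 was low in most libraries labelled no-dox vehicle, where no hairpin should be induced. An exchange of prepared libraries with the dox table is argued against by the share of non-polyadenylated RNAs, at most 0.0161% in these libraries and at least 5.13% in the dox table. An exchange of tumours or RNA before preparation would not show in that share and stays open. An exchange of some labels with the no-dox testosterone group would let another split of these 8 libraries call as many genes, but the labels called 2849 and the highest other split 0. An exchange of all of them would turn the T effect round. Yet of the genes called for T here and in LuCaP 35CR, 732 went in the same and 99 in opposite directions. With the dox table in its place these counts were 358 and 6. Hairpin expression without doxycycline was not tested and may stay open, as does a difference between tumours.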

How the results depend on the processing

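The host score covariate, the length trend and the removal of dox testosterone 3 and 4 were tests chosen only after results were seen. Of 12842 repeats of 559 results for named genes, 12278 kept their direction and side of the threshold, 458 lost the call, 106 gained it and 0 reversed. Of 1830 repeats of 100 list results, 1695 stayed, 124 lost the call, 7 gained it and 4 reversed. Of 272 repeats of the main counts and RB1, 244 stayed. RLE and upper-quartile factors and the stricter filter moved none of these counts by over 1.5 times. The cause was not tested for any change below.

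DESeq2 called 2608 genes for T against vehicle in C4-2 with doxycycline and 164 in the C4-2 interaction, and limma voom called 2017 and 71, where edgeR called 874 and 0. Without a filter edgeR called 1432 and 9. With a block for the tumour number, which the correlations gave no ground to pair, 312 were called with doxycycline.

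With the host score covariate the counts were 0 for C4-2 without doxycycline, 201 with it and 47 for its interaction. In LuCaP 35CR they were 1080 for Pal, 366 for T, 3268 for Pal+T against vehicle and 373 for the interaction. In both C4-2 tables each marker score separated T from vehicle, so the covariate can hardly be told apart from T there. The covariate also reversed the stress list without doxycycline (adjusted p = 0.931) and, with doxycycline, the replication list (adjusted p = 0.0194) and the mitotic list (adjusted p = 0.319). The mitotic list reversed again without dox testosterone 3 and 4 (adjusted p = 0.824).

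Leaving out 1 library gave 1533 to 3894 genes for C4-2 without doxycycline, with 1790 without no-dox vehicle 4 and 1533 without no-dox testosterone 4. With doxycycline it gave 96 to 1935, with 304 without dox vehicle 1, 96 to 120 without dox vehicle 2 to 4, and 1565, 1935 and 228 without dox testosterone 1 to 3. The C4-2 interaction gave 0 to 35, with 35 without dox testosterone 1 and 1 without no-dox vehicle 2. Pal+T against Pal gave 1851 to 3516, with 1851 without Pal 2. The RB1 difference between the C4-2 tables ranged from -1.06 (without no-dox vehicle 4) to -0.61.

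Of 153 list calls, 5 held with an estimated correlation, and 145 to 159 lists were called when 1 library was left out.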

Other observations

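The tests of fewer tumour transcripts, of the host score covariate and of an exchange between Pal and T labels were chosen only after the results were seen.

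Lists not described above also moved. In C4-2 without doxycycline, EMT and TGF-beta genes rose in 10 of 17 cases (median 1.56, camera adjusted p = 1.37e-08, or adjusted p = 0.345 with an estimated correlation) and immediate early genes in 6 of 17 (median 0.68, adjusted p = 0.0018, or adjusted p = 0.345). Fibroblast, endothelial and myeloid markers rose in that comparison as well, and mouse reads were not set apart. With Pal in LuCaP 35CR, luminal genes rose in 7 of 17 cases and fell in 1 (median 0.39, adjusted p = 0.0129, or adjusted p = 0.248).

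Other splits of the same libraries were counted for every comparison. In C4-2, 1 of 35 splits gave as many genes, the real one, both without doxycycline (2849, highest other 0) and with it (874, highest other 0). This is the smallest share that 35 splits allow, so chance is argued against but not excluded. The C4-2 interaction called 0 genes, so 100 of 100 splits give at least as many whatever the data, and the count decides nothing. Its highest other, 5086, had the treatment labels of 1 table reversed, which adds the T effects of both tables. For the LuCaP 35CR interaction 1 of 100 splits, the real one, gave as many as 1374, with a highest other of 853. The drawn splits mix the single effects of Pal and T into the groups. They do not stand for an absent interaction, so this count cannot exclude chance for LuCaP 35CR. For its pairs the 10 splits are too few for a share under 0.05, with 5158, 3835, 7958, 4462 and 2896 genes for Pal, T and Pal+T against vehicle, Pal+T against T and Pal+T against Pal, and 0 as the highest other in each.

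In C4-2 without doxycycline, replication genes were lower with T while fibroblast, endothelial and myeloid genes were higher. Fewer tumour transcripts among the counts would lower luminal genes alike, unless T raised these genes. Their median was 0.069 against -0.67, a difference of 0.74 (bootstrap SE 0.0929 over genes, not over tumours). Scaled over both C4-2 tables, STEAP2 went from 288 ± 41.5 to 506 ± 44.6 CPM with T, while CDH1 was 409 ± 47.5 and 417 ± 25.5. A rise of some luminal genes with T may hide such a loss, so this median cannot decide. With the host score as a covariate the list median went from -0.67 (median SE of its genes 0.165) to -0.528 (0.349), and edgeR called none of its 50 genes, as the SE grew more than the fold shrank. The list's camera adjusted p, 4.59e-13 at the preset correlation, was 0.538 at an estimated one, and 0.345 without the covariate. With libraries thinned to 1 depth its median was -0.62, with 38 of 50 genes called. Fewer tumour transcripts and a part of the host share in this fall thus stay open, as does a slower cycle in tumour cells.

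Androgen-induced genes were higher with Pal alone in LuCaP 35CR. An exchange of single libraries between Pal and T is argued against by MKI67, at most 4.68 CPM in Pal and at least 81.0 in T tumours. Exchanged whole groups would leave the finding, as the list median was 1.62 with T. With the length trend removed (rho from 0.31 to 0.0344) the list median was 1.41, from 1.49. With the host score as a covariate it was 1.29 (median SE of its genes 0.345, from 0.223), with 21 of 40 genes called higher. The list's adjusted p was then 2.05e-22 at the preset and 0.149 at an estimated correlation. A biological effect of Pal on these genes may therefore be a hypothesis. Composition effects that the 3 marker scores miss stay open.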
